A study of Homo sapiens and Mus musculus with 64 samples.

How the data were processed

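RNA-seq libraries from human breast carcinoma cell lines were compared after treatment with the MEK1/2 inhibitor trametinib, the BET bromodomain inhibitor JQ1, or both. The series holds 64 samples in 36 groups, of which 60 are human and 4 are mouse. Processed values were used for the 34 samples that stand behind 6 tables, and the other 30 samples were not analysed here. Per the labels' protocols, total RNA was isolated on Qiagen columns, and all libraries used here were made with the KAPA Stranded mRNAseq kit.

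Each of 4 tables from the submitters held a DESeq2 comparison. In these, the base mean is a signal, the mean of read counts divided by size factors, as the authors deposited it. The log2 fold change and its standard error are on the log2 scale, per the file headers. The Wald statistic is a score, the log2 fold change over its standard error, per the file headers. The p-value and its Benjamini-Hochberg adjusted value are the authors', per the file headers. A further column in 3 of those tables marked 568 genes as kinases and was used for one enrichment. The other 2 tables held a deposited signal per gene and library for SUM159, RSEM estimates that the labels' file title calls normalized. In every library of both the upper quartile of genes above 0 lay between 997 and 999.5, so the values were scaled to a common upper quartile of about 1000 by the authors, a step read from the values and not stated in the labels.

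Per the submitters' processing notes, Picard 1.88, SAMtools 1.2 and RSEM were used for all libraries, with R 3.2.2 and DESeq2 1.12.3 named for the libraries of the SUM159 experiments, and with the human build hg19. The submitters name no DESeq2 version for the 24 libraries of the subtype tables. The aligner and the gene annotation are not given in the sources used here. Genes are reported by symbol and Entrez identifier as the files give them, without coordinates, because the reference used here is of another build. In the SUM159 comparison, 19 of 12091 gene names had been turned into dates and were left out.

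The basal-like table covered HCC1806, the EpCAM/CD49f positive part of SUM149, and MDAMB468. The claudin-low table covered SUM159, HS578T and WHIM12. Each rested on 12 libraries, 2 with DMSO and 2 with 500 nM trametinib at 24 h for each of 3 lines, and the subtype table on all 24. The titles of the 2 SUM159 controls in this set name both DMSO and 500 nM trametinib, and they were read as DMSO. The SUM159 table compared 3 libraries with 100 nM trametinib with 3 with DMSO. No value per library or per line stands in these 4 tables, so they were read as deposited, with a gene called at an adjusted p under 0.05 and no standard deviation of their own. The authors' model formula for the subtype tables is not given. Whether their p-values allow for the spread between lines of a subtype is therefore not known. In 3 of them the standard errors were at most 0.325, 0.583 and 0.637, the range of shrunken fold changes (a step the labels do not state), whereas in the subtype table they reached 6.01. The fold changes of that table ran opposite to basal-like minus claudin-low (r = -0.986 and slope -1.06 across 10589 genes), so they are described here as claudin-low minus basal-like.

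The difference of response between subtypes was tested in addition with a Wald test on the basal-like and claudin-low tables, whose libraries are separate, with Benjamini-Hochberg adjustment over 18020 genes. The overlap of calls and the share of kinases were tested with two-sided Fisher's exact tests across genes, which are not independent replicates.

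The 2 per-library tables, replicates 2 and 3, each held 20530 genes in 1 DMSO library and 1 library each with 100 nM trametinib, 300 nM JQ1 and both drugs for 24 h. Column names were matched to samples by replicate, drug and time, which for the trametinib column of replicate 2 and both combination columns was an inference from abbreviated names. Low values lay on steps of a fixed size in each library, from which 12.5 to 34.7 megareads per library were implied. Between 91.2% and 92.4% of low values came out whole within 0.1 read, too few for a test on counts. Between 0.0323% and 0.0564% of the signal lay in genes without a symbol. Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), with the 4 groups and the table as a block, on 12839 genes with a mean of at least 10. The fit left 3 residual degrees of freedom, to which the moderation added a median of 5.69. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The 6 contrasts were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The labels give the same replicate numbers to all groups, and each number has its own table. Deviations of libraries from their group means correlated between all 6 pairs of groups (r from 0.726 to 0.828 across genes), so the numbers pair the libraries and the block was kept. The labels do not say that replicates are separate cultures, and p-values then measure only the spread between these samples, which may be technical.

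A set of 21 gene lists, a rule for the genes to name, the design and the alternatives below were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and on the deposited Wald scores for the authors' tables. Adjustment was over lists and comparisons of one fit. Over the SUM159 libraries no call held with an estimated correlation, and the smallest adjusted p of the 126 was then 0.14. That correlation was estimated from the 3 residual degrees of freedom of the fit. A list that does not pass there is therefore not shown to be unchanged. The fry test, an alternative, asks whether a list's genes move on balance one way, and its p-value does not compare the list with other genes. Named genes are, for each comparison, the 8 largest rises and falls among called genes with a mean of at least 100 and the same sign in both replicates, up to 4 called members of a list (or 2 as values where none was called), a panel of 12 genes, and, for the response remaining with JQ1, the 8 trametinib-raised genes with the lowest combination over trametinib change. Those 8 were chosen and measured in the fit of both tables. For the medians of that response, genes changed at least 2-fold in one table were measured in the other, because choosing and measuring in the same libraries would give a fall back by chance. Covariance from the shared DMSO library was simulated with 100 sets of unchanged groups. Values of some genes that this rule selects are not reported here.

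Alternatives were a stricter adjusted p of 0.01, a log2 minimum of 1, a base mean minimum of 100, no replicate block, a pseudocount of 5, no filter, quantile and median ratio scaling, plain empirical Bayes, each of 8 libraries left out, a 1.5-fold choice, a preset correlation of 0.05, an estimated correlation and fry. The steps were tested on simulated data. For trametinib against DMSO over 12839 genes, 70 of 100 genes changed by 1 on the log2 scale and 92 of 100 changed by 2 were recovered, with 12 false calls. For the difference between subtypes over 18020 genes, 115 of 200 genes with a difference of 1 were recovered, with 7 false calls. Camera put 2 of 21 unchanged lists under 0.05. The simulated genes varied independently, so this does not check whether the preset correlation is adequate for these data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 served limma.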

Results

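Gene expression was measured by RNA-seq in human breast carcinoma lines treated for 24 h with trametinib, an inhibitor of the kinases MEK1 and MEK2 that activate ERK. As its title states, the series asks how cells adapt to MEK inhibition and whether drugs aimed at P-TEFb, the kinase complex that releases paused RNA polymerase II, lessen this. The drug used for this in the samples analysed here was JQ1, which displaces BET proteins from acetylated chromatin. Basal-like lines (HCC1806, the EpCAM/CD49f positive part of SUM149, and MDAMB468) and claudin-low lines (SUM159, HS578T and WHIM12) each gave 2 DMSO and 2 trametinib libraries per line at 500 nM. SUM159, a claudin-low line with mesenchymal features, was also treated with 100 nM trametinib, 300 nM JQ1 or both. Values per library were used for its replicates 2 and 3, with 1 library per treatment and replicate.

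In replicate 2 the values implied 29.4 megareads for DMSO, 33.6 for trametinib, 34.7 for JQ1 and 31.3 for both drugs. In replicate 3 they implied 14.9, 20.6, 12.5 and 20.6 megareads in the same order. A single read was worth between 0.461 and 1.19 normalized units, so values of a few units rest on a few reads. Between 14797 and 16169 genes lay above 0 in a library, and the 10 most abundant genes took 4.17% to 8.63% of the signal. The depth of the libraries of the subtype tables and of SUM159 replicate 1 was not analysed here.

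The first comparison asks how basal-like lines respond to MEK inhibition. Trametinib lowered ERK output and ribosome biogenesis genes, and raised interferon, antigen presentation, sterol synthesis and lysosome genes. In the authors' deposited table for these lines, the largest fall on the log2 scale was in SPRY4 (-6.18, SE 0.23; Entrez 81848), a feedback inhibitor of receptor signalling to RAS. The ETS factors ETV5 (-4.91), ETV4 (-4.13) and ETV1 (-3.82) were also among the 8 largest falls in the authors' deposited table. The early growth response factor EGR1 (-4.55), the ERK phosphatases DUSP6 (-3.28, SE 0.31; Entrez 1848) and DUSP4 (-2.81), and the AP-1 subunit FOSL1 (-3.18) completed the 8 largest falls in the authors' deposited table. Among the 8 largest rises in the authors' deposited table were the matrix proteoglycan decorin, DCN (3.37, SE 0.23), the ferritin receptor SCARA5 (2.35), complement factor B, CFB (2.11), and the BH3-only cell death gene BMF (2.04). They also held TCHHL1 (2.04), the intracellular channel protein CLIC3 (1.99), the fibrillar collagen COL5A2 (1.96) and the myosin light chain MYL9 (1.85), in the authors' deposited table. The growth regulators MYC (-1.22) and CCND1, cyclin D1 (-1.55), and the receptor AXL (-0.69) fell, and the collagen receptor DDR1 (0.54) rose, in the authors' deposited table. PDGFRB (0.62, adjusted p = 0.10), EGFR (-0.26, adjusted p = 0.23) and HEXIM1 (-0.02, adjusted p = 0.90) did not pass in the authors' deposited table. The base mean of PDGFRB was only 7.02 there, so its change in these lines is poorly measured.

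By the adjusted p of the authors' deposited table, 3698 of 15818 tested genes were higher and 3306 lower in basal-like lines with trametinib, and 382 and 157 of them by at least 1 on the log2 scale. Of the ERK output and feedback list, 28 of 32 members fell and 1 rose (28 and 2 adjusted over the list alone), with a camera adjusted p of 3.6e-54 on the authors' deposited table. All 31 members of the ribosome biogenesis and MYC target list fell in the authors' deposited table (31 adjusted over the list alone; p = 3.6e-21). They held the polyamine enzyme ODC1 (-1.09) and the RNA polymerase III subunit POLR3G (-0.99), as the authors' deposited table gives them. In the interferon list 28 of 30 members rose and none fell (28 adjusted over the list alone; p = 6.8e-14), led by SAMD9L (1.59) and XAF1 (1.47) in the authors' deposited table. Antigen presentation had 16 of 22 members higher (17 adjusted over the list alone; p = 4.5e-08), among them HLA-F (1.04) and the immunoproteasome subunit PSMB9 (1.01), in the authors' deposited table. In the authors' deposited table, 21 of 25 sterol synthesis genes rose and 1 fell (22 and 1 adjusted over the list alone; p = 8.5e-06). In the authors' deposited table, 21 of 29 lysosome and autophagy genes rose and 1 fell (23 and 1 adjusted over the list alone; p = 6.9e-06). The KLF and growth arrest list had 15 of 23 members higher (16 adjusted over the list alone; p = 3.1e-05), with TP53INP1 at 1.35 and the CDK inhibitor CDKN2B at 1.02 in the authors' deposited table. Of the E2F and DNA replication genes, 17 of 32 fell and 1 rose in the authors' deposited table (17 and 1 adjusted over the list alone; p = 0.00038). Their median was -0.23 and the largest fall -0.77 in CDC25A, a phosphatase that activates CDKs, in the authors' deposited table. Another 3 lists passed camera on the authors' deposited table at a preset correlation of 0.01 but not at 0.05. In the authors' deposited table these were inflammatory cytokine genes (10 lower and 5 higher of 24, or 11 and 7 adjusted over the list alone; p = 0.024 and 0.12). Epithelial and keratin genes had 16 higher and 4 lower of 30 (likewise adjusted over the list alone; p = 0.037 and 0.17) in the authors' deposited table. Matrix genes had 15 higher and 6 lower of 28 (16 and 6 adjusted over the list alone; p = 0.0043 and 0.053) in the authors' deposited table.

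The other 10 lists did not pass in basal-like lines. On the authors' deposited table their camera adjusted p was 0.057 for mitosis, 0.13 each for BET and P-TEFb components, AP-1 factors and polyadenylated histones, and 0.43 for receptor ligands. On the authors' deposited table it was 0.45 each for leukocyte and endothelial markers and housekeeping genes, 0.79 for receptor tyrosine kinases, 0.81 for mesenchymal factors and 0.85 for the BCL2 family. In the mitosis list, 9 of 30 members fell and 2 rose (9 and 1 adjusted over the list alone), with a median of -0.06 in the authors' deposited table.

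The claudin-low lines were compared in the same way. Trametinib lowered ERK output genes together with all tested genes of the E2F and mitosis lists, and raised matrix, sterol, interferon and growth arrest genes. The 8 largest falls in the authors' deposited table for these lines held ETV5 (-5.84, SE 0.14), MYEOV (-5.66), DUSP6 (-5.64, SE 0.34), EGR1 (-5.36), SPRY4 (-5.24), the neutrophil chemokine IL8 (-5.23), ETV4 (-4.10) and the pentraxin PTX3 (-4.02). Among the largest rises in the authors' deposited table were those of cardiac actin ACTC1 (4.40), CLIC3 (4.34) and the small heat shock protein CRYAB (4.26). Next came, in the authors' deposited table, the matricellular gene WISP2 (3.86), BMF (3.61), FAM198B (3.43) and the glucose-responsive transcription factor MLXIPL (3.37). Among the panel genes in the authors' deposited table, FOSL1 (-3.19), CCND1 (-2.82), MYC (-0.89) and EGFR (-0.37) fell. DDR1 (1.93, SE 0.31), PDGFRB (1.96, SE 0.26), a platelet-derived growth factor receptor, and HEXIM1 (0.52), which holds P-TEFb in an inactive complex, rose in the authors' deposited table. AXL stood at -0.05 (adjusted p = 0.81) in the authors' deposited table.

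Of 18553 genes tested, 5350 were higher and 3990 lower in the authors' deposited table for claudin-low lines, and 1613 and 795 of them by at least 1 on the log2 scale. All 32 E2F and DNA replication genes fell (32 adjusted over the list alone; camera p = 1.8e-16), with a median of -2.07 and cyclin E2, CCNE2, at -2.85 in the authors' deposited table. All 30 mitosis genes fell too (30 adjusted over the list alone; p = 6.2e-10), with CDK1, the mitotic kinase, at -2.17 in the authors' deposited table. The authors' deposited table had 27 of 32 ERK output genes lower and 1 higher (27 and 2 adjusted over the list alone; p = 8.3e-43). Of 31 ribosome biogenesis genes 30 were lower (30 adjusted over the list alone; p = 5.3e-22) in the authors' deposited table. Sterol synthesis genes rose in 22 of 25 cases (22 adjusted over the list alone; p = 7.0e-08), with HMGCS1, an early enzyme of the mevalonate pathway, at 1.40 in the authors' deposited table. In the matrix list of the authors' deposited table, 19 of 31 members rose and 4 fell (19 and 4 adjusted over the list alone; p = 0.00065), among them DCN (3.17), COL3A1 (2.35) and lumican, LUM (2.27). Interferon genes rose in 22 of 30 cases (23 adjusted over the list alone; p = 5.9e-05), with MX2 at 1.84 in the authors' deposited table. Antigen presentation genes rose in 14 of 22, with 1 lower (14 and 1 adjusted over the list alone; p = 0.0036), in the authors' deposited table. Lysosome genes rose for 24 of 29 (24 and 1 lower adjusted over the list alone; p = 0.00038) in the authors' deposited table. Growth arrest genes rose for 16 of 23 with 2 lower (17 and 2 adjusted over the list alone; p = 0.0023), with CDKN1C, the CDK inhibitor p57, at 2.85 in the authors' deposited table. Mesenchymal factors (12 higher and 1 lower of 27, or 11 and 1 adjusted over the list alone; p = 0.021) passed at a preset correlation of 0.01 but not at 0.05 (p = 0.12) on the authors' deposited table.

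Camera adjusted p on the authors' deposited table for the 10 other lists in claudin-low lines was 0.090 for polyadenylated histones, 0.13 for epithelial genes, 0.26 for inflammatory cytokines, 0.43 for receptor tyrosine kinases, and 0.44 for AP-1 factors. On the authors' deposited table it was 0.79 for leukocyte and endothelial markers, 0.87 each for the BCL2 family and housekeeping genes, 0.90 for receptor ligands and 0.93 for BET and P-TEFb components. The median, mean and test of receptor ligands, AP-1 factors and the BCL2 family differed in sign in the authors' deposited table. Of 56 receptor tyrosine kinases, 16 rose and 10 fell (16 and 10 adjusted over the list alone), with ERBB4 (2.75) and ROS1 (2.45) among those that rose in the authors' deposited table.

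Calls in the 2 sets of lines overlapped. Of 15713 genes tested in both of the authors' deposited tables, 2664 were higher in both, against 1207 for independent lists (odds ratio 10.0), and 2405 were lower in both, against 831 (odds ratio 18.8). By contrast, 76 genes were higher in basal-like and lower in claudin-low lines and 102 the reverse, against 929 and 1080, in the authors' deposited tables. Genes marked as kinases in the authors' deposited tables passed no test of their share of calls against other genes. Of 527 tested in basal-like lines, 129 were higher (24.5%) and 94 lower (17.8%), and of 563 in claudin-low lines 179 were higher (31.8%) and 118 lower, in the authors' deposited tables. Fisher's exact test gave adjusted p of 0.71, 0.24, 0.24 and 0.79 for these shares in the authors' deposited tables.

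**Figure D1:**
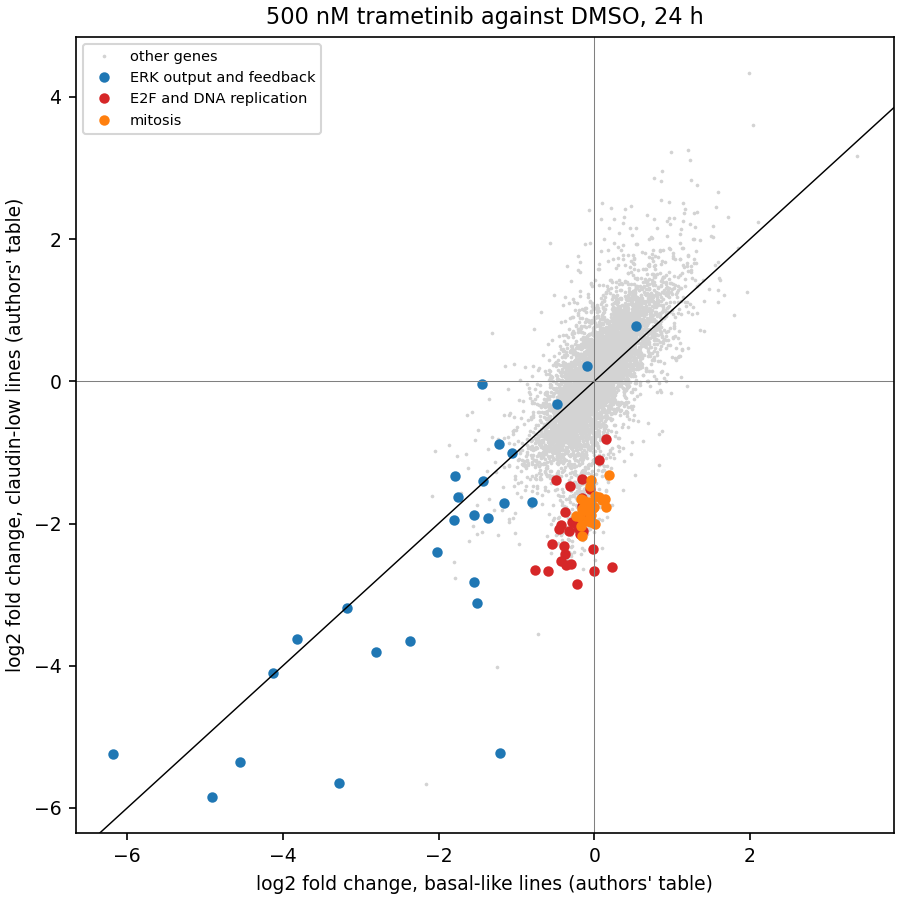
Log2 fold change with 500 nM trametinib over DMSO at 24 h in basal-like lines (x axis) and claudin-low lines (y axis) for genes with a base mean of at least 100 in both of the authors' deposited tables. Each point is a gene, ERK output genes are blue, E2F genes red and mitosis genes orange, and the line marks an equal response. E2F and mitosis genes lie below the line, with medians of -0.23 and -0.06 on the x axis and -2.07 and -1.78 on the y axis.

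The next comparison asks which responses differed between the subtypes. Each subtype was represented by 3 lines, so a difference called here may be one between single lines. The fall of DNA replication and mitosis genes was larger in claudin-low lines, as was that of IL8 and CXCL1, while the changes of LAMA3 and CLIC3 were more positive there. In a Wald test on the difference of the authors' deposited tables, basal-like minus claudin-low was positive for IL8 (4.02, SE 0.50), MYEOV (3.50), and the replication regulators E2F2 (2.84), E2F8 (2.66) and CCNE2 (2.63). It was also positive, from the authors' deposited tables, for the chemokine CXCL1 (2.82), PTX3 (2.77) and the tight junction gene CLDN1 (2.53). It was negative for the laminin chain LAMA3 (-2.52, SE 0.29), C1orf198 (-2.48), DEPDC6 (-2.41), an mTOR-binding protein, and CLIC3 (-2.35), from the authors' deposited tables. Further negative values from the authors' deposited tables were in C10orf10 (-2.24), the calcineurin regulator RCAN2 (-2.22), the kinesin KIF26B (-2.20) and EFHD1 (-2.09). In all, 3492 of 18020 genes differed at an adjusted p under 0.05 over the authors' deposited tables, 1600 with the higher and 1892 with the lower change in basal-like lines. The fold changes that this test subtracts were read as shrunken, and unequal shrinkage could make or hide a difference.

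The subtype table of the authors tested the same difference over all 24 libraries, here read as claudin-low minus basal-like. The authors' deposited table called 2144 genes higher and 1685 lower of 15149. Among the largest positive values in the authors' deposited table were those of the calcium buffer CALB1 (4.78) and the phosphatase DUSP2 (4.26). They were followed in the authors' deposited table by MLXIPL (4.15), the actin bundler ESPN (4.13), the growth factor PDGFB (4.09) and the neurotensin receptor NTSR1 (3.85). Negative values in the authors' deposited table were largest in IL8 (-4.06), FAM111B (-3.79), SERPINB4 (-3.55), RNF17 (-3.53), MYB (-3.47), E2F2 (-3.21), E2F8 (-3.18) and CXCL1 (-3.12). All 32 E2F genes (32 adjusted over the list alone; median -2.01, camera p = 4.7e-32) were lower in claudin-low lines in the authors' deposited table. So were all 30 mitosis genes (30 adjusted over the list alone; median -2.09, p = 1.1e-25) in the authors' deposited table. Polyadenylated histones were lower for 10 of 24 members (10 adjusted over the list alone; p = 0.00021) in the authors' deposited table. Sterol synthesis genes (10 of 25 higher, likewise adjusted over the list alone) and ribosome biogenesis genes (5 of 31 lower, or 3 adjusted over the list alone) each had p = 0.016 in the authors' deposited table. At a preset correlation of 0.05 these became 0.11 and 0.12 on the authors' deposited table. Of the genes called by the Wald test, 3221 were called in the same direction by the authors' deposited table and 0 in the opposite one. This is no independent support, since both tests use the same 24 libraries. The direction of the subtype table was also read from its match with the difference tested here.

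For some panel genes the 2 tests differed in call. DUSP6 passed the Wald test (basal-like minus claudin-low 2.36, adjusted p = 1.0e-05) but stood at -0.52 (adjusted p = 0.61) for claudin-low minus basal-like in the authors' deposited table. CCND1 had 1.28 (adjusted p = 0.028) by the Wald test and -0.87 (adjusted p = 0.26) in the authors' deposited table. PDGFRB had -1.34 (adjusted p = 0.0094) by the Wald test and 1.05 (adjusted p = 0.13) in the authors' deposited table. Its base mean was 7.02 in basal-like and 2713 in claudin-low lines, so its difference of response is poorly measured. SPRY4 had -0.95 (adjusted p = 0.10) by the Wald test and 1.85 (adjusted p = 0.013) in the authors' deposited table. Both called DDR1 (-1.39 by the Wald test and 1.55 in the authors' deposited table), AXL (-0.64 and 0.69) and HEXIM1 (-0.54 and 0.56), and neither called ETV4, FOSL1, MYC or EGFR.

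The response of SUM159 to the lower dose of 100 nM was given by the authors over 3 libraries per group. Cell cycle, ERK output and ribosome biogenesis genes fell, and matrix, interferon and lysosome genes rose. The largest rises in the authors' deposited table were in angiotensinogen, AGT (6.54, SE 0.44), ANGPTL7 (5.97), CSDC2 (5.75), and the adhesion receptor GPR56 (5.62). Rises followed in the authors' deposited table in CLEC3B (5.36), OLFML3 (5.32), CRYAB (5.08) and IGFBP5 (5.00), which binds insulin-like growth factors. The largest falls in the authors' deposited table were in EGR1 (-5.10, SE 0.38), IL8 (-4.44), PTX3 (-4.01) and E2F8 (-4.00). Falls followed in the authors' deposited table in FAM72D (-4.00), the recombination gene XRCC2 (-3.99), C11orf82 (-3.97) and the ribonucleotide reductase subunit RRM2 (-3.96). DDR1 (3.36), PDGFRB (3.24) and HEXIM1 (0.79) rose, and DUSP6 (-2.82), SPRY4 (-2.56), ETV4 (-3.75), FOSL1 (-3.36) and MYC (-0.98) fell in the authors' deposited table. CCND1 (-0.81, adjusted p = 0.067), AXL (0.33, adjusted p = 0.57) and EGFR (-0.05, adjusted p = 0.90) did not pass in the authors' deposited table.

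Of 11963 genes, 2480 were higher and 2481 lower in the authors' deposited table for 100 nM. All 32 E2F genes (32 adjusted over the list alone; camera p = 3.2e-34) and all 30 mitosis genes (30 adjusted over the list alone; p = 1.4e-45) fell in the authors' deposited table. So did 30 of 31 ribosome biogenesis genes (31 adjusted over the list alone; p = 5.0e-19) in the authors' deposited table. ERK output genes fell for 19 of 27, with 2 higher (22 and 2 adjusted over the list alone; p = 1.6e-07), in the authors' deposited table. The authors' deposited table had 14 of 23 matrix genes higher (15 adjusted over the list alone; p = 2.1e-05) and 12 of 23 interferon genes (13 adjusted over the list alone; p = 6.4e-05). Also higher in the authors' deposited table were 22 of 28 lysosome genes with 1 lower (22 and 1 adjusted over the list alone; p = 1.9e-07). Receptor tyrosine kinases rose as a list (11 higher and 2 lower of 28, likewise adjusted over the list alone; p = 0.016) at a preset correlation of 0.01 but not at 0.05 (p = 0.11) on the authors' deposited table.

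In the libraries of replicates 2 and 3, trametinib alone lowered ERK output and cell cycle genes in SUM159 and raised DDR1 and PDGFRB. The DMSO and trametinib libraries of these replicates are 4 of the 6 behind the 100 nM table, so the 2 are not separate tests. DUSP6 went from 228.9 and 221.7 normalized units with DMSO to 5.38 and 4.70 with trametinib (log2 -5.23, SE 0.32). DDR1 went from 283 and 289 to 4465 and 3977 (3.88, SE 0.16; 14.7-fold). PDGFRB rose by 3.53 (SE 0.19; 11.5-fold). The 8 largest rises were in ANGPTL7 (8.33, SE 0.66), AGT (7.86), LCNL1 (7.78), and the inducible heat shock gene HSPA1A (7.66), followed by the dipeptidase DPEP1 (7.64), IGFBP5 (7.42), the folate receptor FOLR1 (7.41) and CSDC2 (7.37), all near 0 with DMSO. HSPA1A was listed at 0 in both DMSO libraries and at 616.4 and 65.4 with trametinib. Since it has a near-identical copy, its values are uncertain. The 8 largest falls were in FAM111B (-5.78), EGR1 (-5.70), ETV4 (-5.52), the replication factor MCM10 (-5.42), ETV5 (-5.40), DUSP6, MYEOV (-5.21) and the EGFR ligand AREG (-5.09). SPRY4 (-4.38), FOSL1 (-4.31), CCND1 (-1.02) and MYC (-0.95) fell, and AXL (0.74) and HEXIM1 (0.96) rose. EGFR (0.22, adjusted p = 0.20) did not pass in limma.

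By limma with Benjamini-Hochberg adjustment, 4743 of 12839 genes were higher and 2439 lower with trametinib, a share of 66.0% higher. That share became 51.5% under median ratio scaling (3602 and 3396 genes) and 49.9% under quantile scaling (3361 and 3379 genes). The median gene moved by 0.24 and 0.27 on the log2 scale in replicates 2 and 3 as deposited, and by 0.03 and 0.04 under median ratio scaling. List medians are therefore given against 0.26 for all genes. All 32 E2F genes (32 adjusted over the list alone; median -3.11, camera p = 4.4e-25, adjusted p = 0.14 with an estimated correlation) fell. All 30 mitosis genes fell too (30 adjusted over the list alone; median -3.41, p = 1.4e-24, adjusted p = 0.34 with an estimated correlation). ERK output genes fell for 23 of 29, with 3 higher (23 and 3 adjusted over the list alone; median -2.10, p = 7.5e-10, adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis genes fell for 31 of 31 (31 adjusted over the list alone; median -1.36, p = 1.8e-17, adjusted p = 0.27 with an estimated correlation). Interferon genes rose in 18 of 25 cases (18 adjusted over the list alone; p = 0.00072, adjusted p = 0.34 with an estimated correlation), with STAT2 at 3.02. Matrix genes rose in 17 of 23, with 1 lower (17 and 1 adjusted over the list alone; median 1.62, p = 0.00033, adjusted p = 0.17 with an estimated correlation). Without the replicate block, 2860 genes were called, and the calls of MYC (adjusted p = 0.17, and 0.00084 to 0.17 over its alternatives; log2 -0.56 without DMSO replicate 2) and AXL (adjusted p = 0.53, and 0.0023 to 0.53) ended. The call of HSPA1A ended without DMSO replicate 2 (adjusted p = 0.12), trametinib replicate 2 (0.14), trametinib replicate 3 (0.18), the filter (0.052) or the block (0.10), with 0.00031 to 0.18 over its alternatives. A library left alone in its group when its partner is left out is assumed to vary like those of the other groups.

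**Figure D2:**
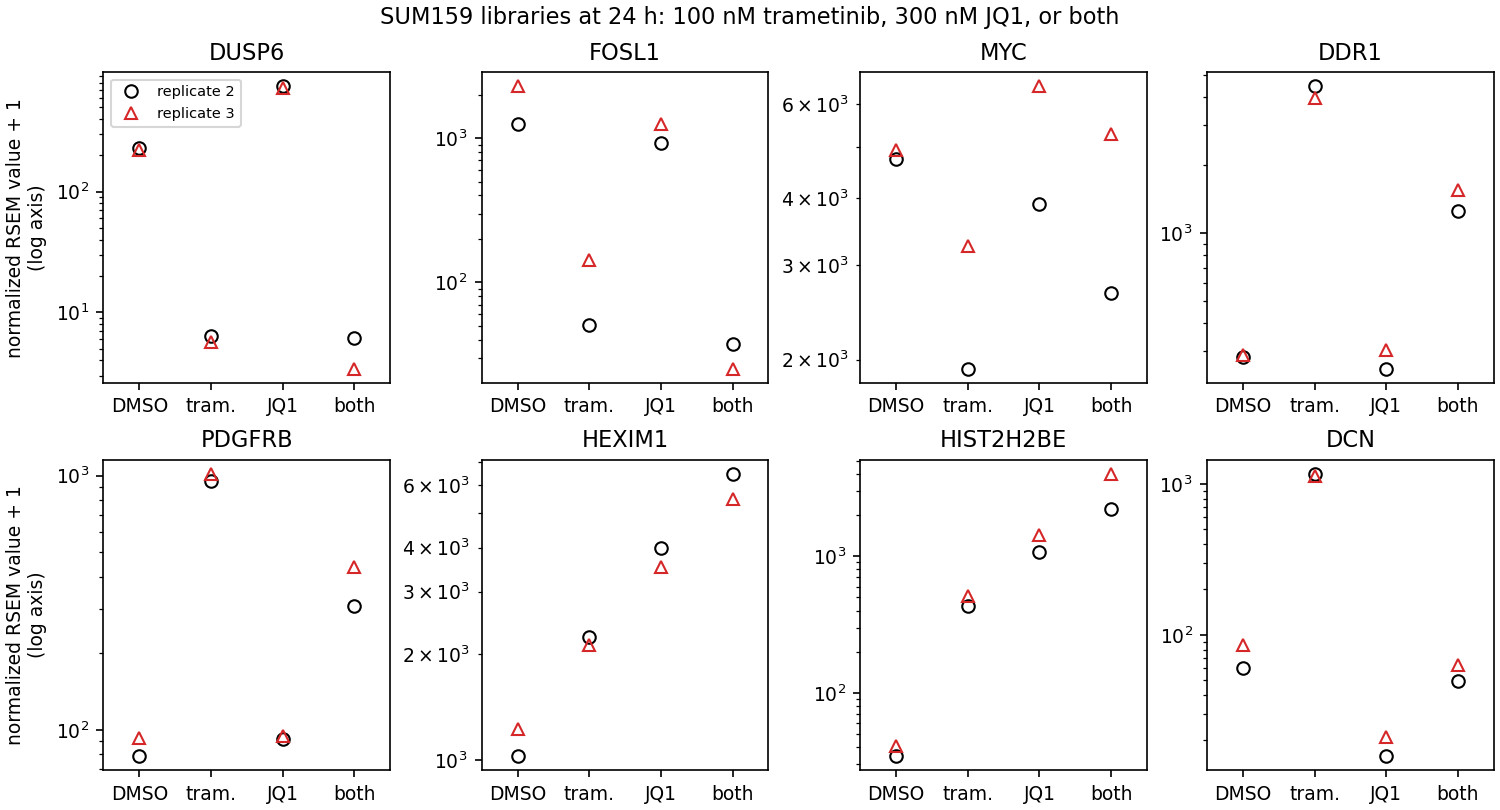
Normalized expression plus 1 on a log axis for 8 genes in SUM159 after 24 h with DMSO, 100 nM trametinib, 300 nM JQ1 or both, with circles for replicate 2 and triangles for replicate 3, each point 1 library. DDR1 lies at 283 and 289 with DMSO, 4465 and 3977 with trametinib, and 1250 and 1558 with both drugs.

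JQ1 alone raised histone and growth arrest genes in SUM159 and lowered replication and mitosis genes, CD36, ACSL5 and COL3A1. HEXIM1, a gene widely used as a readout of BET inhibition, went from 1026 and 1221 units with DMSO to 3994 and 3529 with JQ1 (1.75, SE 0.15; 3.35-fold). The 8 largest rises were in the histones HIST2H4A (5.07), HIST2H2BE (5.04, SE 0.18), HIST2H2AA3 (4.56) and HIST1H4H (3.77), the water channel AQP3 (4.92), DPYSL3 (4.16), SCARA5 (3.98, or 2.41 with a pseudocount of 5) and the calpain CAPN5 (3.75). HIST2H4A and HIST2H2AA3 have near-identical copies, so their values are uncertain. The 8 largest falls were in the stress factor NUPR1 (-4.33, SE 0.35), the estrogen sulfotransferase SULT1E1 (-3.97), the fatty acid receptor CD36 (-3.94), and the acyl-CoA synthetase ACSL5 (-3.80). Next came the phosphatase PTPN22 (-3.78), the cytokine signalling inhibitor SOCS2 (-3.65), reelin, RELN (-3.63), and COL3A1 (-3.58). DUSP6 (1.69) and CCND1 (0.74) rose. DDR1 (-0.05), PDGFRB (0.13), MYC (0.06), AXL (0.07), EGFR (-0.07), SPRY4 (0.28), ETV4 (-0.92) and FOSL1 (-0.65) did not pass in limma (adjusted p from 0.16 for ETV4 to 0.85 for MYC). ETV4 passed without combination replicate 2 (0.037) or 3 (0.030), with 0.030 to 0.69 over its alternatives.

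In limma, 1982 genes were higher and 1961 lower with JQ1. The libraries were scaled to a common upper quartile, so a fall of all genes together would not show in these counts. Polyadenylated histones rose for 19 of 21 members (19 adjusted over the list alone; median 2.66, camera p = 4.7e-15, adjusted p = 0.14 with an estimated correlation). Growth arrest genes rose for 14 of 22 (15 and 1 lower adjusted over the list alone; median 0.82, p = 9.7e-06, adjusted p = 0.14 with an estimated correlation), among them TP53INP1 (3.30) and TXNIP (3.24). Lysosome genes rose for 13 of 28 (13 adjusted over the list alone; median 0.41, p = 0.00048, adjusted p = 0.52 with an estimated correlation). E2F genes fell for 30 of 32 (30 adjusted over the list alone; median -1.39, p = 2.9e-16, adjusted p = 0.14 with an estimated correlation), and mitosis genes for 26 of 30 (29 adjusted over the list alone; median -1.08, p = 7.1e-13, adjusted p = 0.45 with an estimated correlation). Ribosome biogenesis genes fell for 21 of 31, with 1 higher (22 and 1 adjusted over the list alone; median -0.59, p = 3.2e-06, adjusted p = 0.43 with an estimated correlation). The count of 3943 genes fell to 1465 without JQ1 replicate 2, 2405 without DMSO replicate 3, 1010 without JQ1 replicate 3 and 118 without the replicate block. The call of CCND1 ended without these libraries (adjusted p = 0.051, 0.062 and 0.12 in the same order) and the block (0.15), with 0.0067 to 0.15 over its alternatives. That of DUSP6 ended without JQ1 replicate 2 (0.054), JQ1 replicate 3 (0.097) and the block (0.097), with 0.0025 to 0.097. Without the block the calls of CD36 (0.30), COL3A1 (0.26), DPYSL3 (0.093) and SULT1E1 (0.056) ended as well, with 0.00040, 0.0011, 7.5e-05 and 7.1e-05 as the lowest over their alternatives.

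With both drugs, against DMSO, SUM159 had low mitosis genes, with histones, CDKN1C and AQP3 high. The 8 largest rises were in SCARA5 (8.84), CDKN1C (7.74, SE 0.22), AQP3 (7.52), CLIC3 (6.59), GPR56 (6.40), HIST2H2BE (6.32), AGT (6.14) and HIST2H2AA3 (5.80). CDKN1C went from 76.8 and 67.6 units with DMSO to 21879 and 11075 (213-fold). The 8 largest falls were in E2F2 (-7.00), MCM10 (-6.87), FAM111B (-6.75), SPRY4 (-6.70), the centromere genes HJURP (-6.25) and SPC25 (-6.00), the replication factor CDC45 (-5.98) and TMEM156 (-5.94). DDR1 (2.28), PDGFRB (2.10), HEXIM1 (2.41) and AXL (0.58) rose, and DUSP6 (-5.63), ETV4 (-5.89), FOSL1 (-5.78) and CCND1 (-1.24) fell. MYC (-0.37) and EGFR (-0.18) did not pass in limma (adjusted p = 0.16 and 0.30). The size for MYC depended on a single library, with -0.76 without DMSO replicate 3. Limma called 4015 genes higher and 3202 lower. The histone list had 19 of 21 members higher (19 adjusted over the list alone; median 3.36, camera p = 1.2e-08, adjusted p = 0.14 with an estimated correlation). The mitosis list had all 30 lower (30 adjusted over the list alone; median -4.44, p = 7.3e-22, adjusted p = 0.34 with an estimated correlation). Without the replicate block 3167 genes were called. The call of AXL ended without the block (adjusted p = 0.64), DMSO replicate 3 (0.066) and combination replicate 3 (0.074), with 0.0086 to 0.64 over its alternatives. MYC passed without DMSO replicate 3 (0.0069, with 0.0069 to 0.92).

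Against trametinib alone, adding JQ1 lowered the receptors DDR1 and PDGFRB and 20 of 30 mitosis genes, and raised HEXIM1 and 18 of 21 histones. DDR1 fell from 4465 and 3977 units to 1250 and 1558 (-1.59, SE 0.16), still above its 283 and 289 with DMSO. PDGFRB fell from 948 and 1017 to 307 and 436 (-1.42, SE 0.19). The 8 largest falls were in ANGPTL7 (-8.57, SE 0.66), FAM180A (-6.87), the WNT-induced gene WISP1 (-6.58), DPEP1 (-5.78), CD36 (-5.36), ACSL5 (-5.27), the growth factor IGF2 (-5.13) and DCN (-4.37). DCN went from 1170 and 1132 units with trametinib to 48.3 and 62.0 with both drugs. The 8 largest rises were in the long noncoding RNA UCA1 (4.51, SE 0.48), HIST2H4A (3.67), SCARA5 (3.46), the arrestin family gene ARRDC4 (3.31), CDKN1C (3.10), HIST2H2BF (3.08), HIST1H2BD (3.03) and HIST2H2AA3 (3.02). HEXIM1 rose by 1.45 (2.73-fold), and SPRY4 (-2.32) and FOSL1 (-1.48) fell. Their sizes depended on single libraries, with -0.99 and -0.72 without combination replicate 3 and -0.86 for FOSL1 without trametinib replicate 3. That of ETV4 went from -0.37 to -1.25 without combination replicate 2. DUSP6 (-0.40), ETV4 (-0.37), CCND1 (-0.22), AXL (-0.16), EGFR (-0.41, adjusted p = 0.065) and MYC (0.58, adjusted p = 0.070) did not pass in limma. MYC passed under median ratio scaling (0.036) and without DMSO replicate 2 (0.016) or 3 (0.015), with 0.015 to 0.60 over its alternatives. EGFR passed without DMSO replicate 2 (0.037) or 3 (0.036), with 0.036 to 0.63, and ETV4 without combination replicate 2 (0.0499), with 0.0499 to 0.91.

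Limma called 917 genes higher and 2231 lower with both drugs than with trametinib, 29.1% of them higher. The share was 48.9% under median ratio scaling (1623 and 1693 genes) and 51.4% under quantile scaling (1402 and 1328 genes). The median gene stood at -0.13. Histones rose for 18 of 21 members (18 adjusted over the list alone; median 2.20, camera p = 5.6e-20, adjusted p = 0.14 with an estimated correlation). Growth arrest genes rose for 8 of 22 with 2 lower (11 and 2 adjusted over the list alone; median 0.51, p = 3.2e-06, adjusted p = 0.14 with an estimated correlation). Mitosis genes fell for 20 of 30 (24 adjusted over the list alone; median -1.07, p = 5.6e-08, adjusted p = 0.53 with an estimated correlation). Antigen presentation genes fell for 9 of 16 (11 adjusted over the list alone; median -0.70, p = 0.0023, adjusted p = 0.34 with an estimated correlation) and interferon genes for 12 of 25 with 2 higher (14 and 3 adjusted over the list alone; median -1.05, p = 0.023, adjusted p = 0.13 at a preset correlation of 0.05 and 0.45 with an estimated correlation). Matrix genes fell for 8 of 23 with 1 higher (9 and 1 adjusted over the list alone; median -0.40, p = 0.040, adjusted p = 0.16 at a preset correlation of 0.05 and 0.34 with an estimated correlation). The BET and P-TEFb list had 5 of 29 members higher (3 adjusted over the list alone; median 0.10, p = 0.0087, adjusted p = 0.084 at a preset correlation of 0.05 and 0.48 with an estimated correlation), among them BRD2 (1.80) and AFF1 (0.93), a scaffold of the super elongation complex. The count of 3148 genes fell to 1473 without trametinib replicate 2, 1964 without combination replicate 2, 1237 without trametinib replicate 3, 1033 without combination replicate 3 and 12 without the replicate block. In the last fit the calls of DDR1 and HEXIM1 (both adjusted p = 0.056, from 0.00069 and 0.00026 at the lowest) and PDGFRB (0.075, from 0.0020) ended. So did those of UCA1 (0.39), ARRDC4 (0.30), WISP1 (0.26), CD36 (0.23), DPEP1 (0.13), SCARA5 (0.078), HIST2H2BF (0.075), FAM180A (0.068), HIST1H2BD (0.065), CDKN1C (0.056) and HIST2H2AA3 (0.052), whose lowest values over their alternatives ran from 3.5e-05 for HIST1H2BD to 0.0017 for DPEP1. The call of FOSL1 ended without trametinib replicate 3 (0.21), combination replicate 3 (0.19), under quantile scaling (0.14), plain empirical Bayes (0.084) or no block (0.27), with 0.0086 to 0.27 over its alternatives. That of SPRY4 ended without trametinib replicate 2 (0.19), trametinib replicate 3 (0.29), combination replicate 3 (0.057), under quantile (0.14) or median ratio scaling (0.056), plain empirical Bayes (0.079) or no block (0.23), with 0.0017 to 0.29. That of IGF2 ended without trametinib replicate 2 (0.080), combination replicate 3 (0.090) or the block (0.39), with 0.0094 to 0.39.

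**Figure D3:**
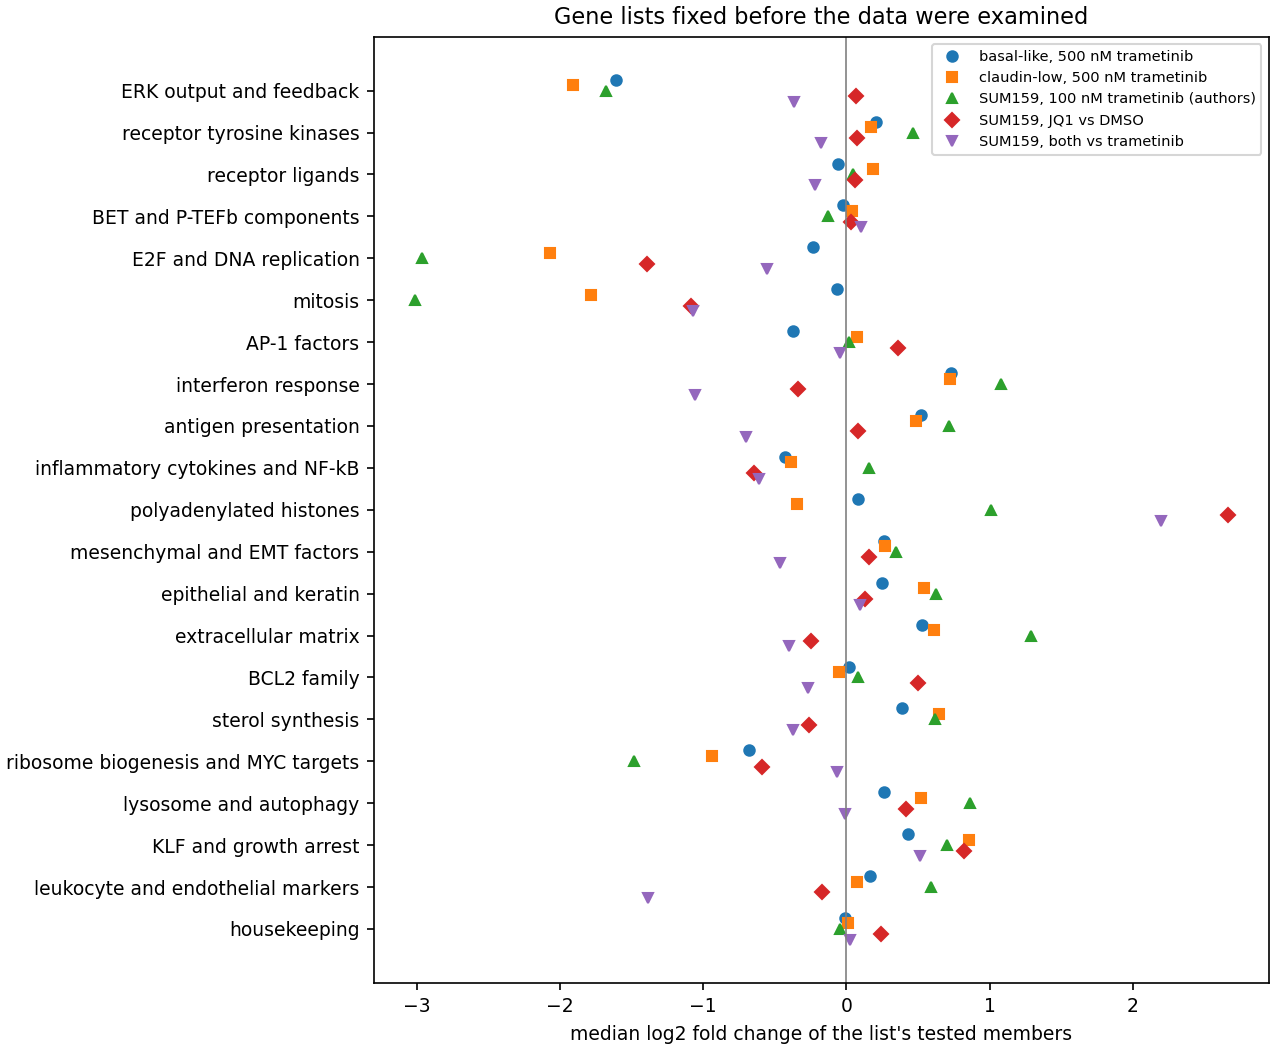
Median log2 fold change of the members of 21 gene lists in 5 comparisons: 500 nM trametinib in basal-like and in claudin-low lines, 100 nM trametinib in SUM159 (all from the authors' deposited tables), and JQ1 against DMSO and both drugs against trametinib in SUM159. E2F genes lie at -0.23, -2.07, -2.96, -1.39 and -0.56 in this order, and polyadenylated histones at 2.66 with JQ1 and 2.20 with both drugs against trametinib.

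Against JQ1 alone, adding trametinib lowered ERK output genes and raised matrix genes, DDR1 and PDGFRB. The 8 largest falls were in DUSP6 (-7.32, SE 0.32), SPRY4 (-6.99), EGR1 (-5.61), the polo-like kinase PLK3 (-5.61), MYEOV (-5.60), AREG (-5.57), FOSL1 (-5.14) and MCM10 (-5.11). DUSP6 went from 742.2 and 719.7 units with JQ1 to 5.11 and 2.41 with both drugs. The 8 largest rises were in CRYAB (7.62, SE 0.61), BEST2 (6.51), IGFBP5 (6.11), and the prostaglandin synthase PTGDS (6.02). They were followed by the amino acid transporter SLC7A7 (5.79), the placental phosphatase ALPP (5.56), AGT (5.52) and the basal keratin KRT5 (5.52). DDR1 (2.34), PDGFRB (1.97), HEXIM1 (0.67) and AXL (0.51) rose, and CCND1 (-1.98) and ETV4 (-4.97) fell. MYC (-0.43, adjusted p = 0.15) and EGFR (-0.11) did not pass in limma. Limma called 2176 genes higher and 1658 lower. Of 29 ERK output genes 21 fell and 1 rose (23 and 1 adjusted over the list alone; median -2.20, camera p = 4.7e-15, adjusted p = 0.14 with an estimated correlation). Of 23 matrix genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.18, p = 4.9e-05, adjusted p = 0.14 with an estimated correlation). The count of 3834 genes fell to 1419 without JQ1 replicate 2, 2104 without combination replicate 2, 1684 without JQ1 replicate 3, 2322 without combination replicate 3 and 509 without the replicate block. The call of HEXIM1 ended without JQ1 replicate 2 (adjusted p = 0.063), combination replicate 2 (0.087), JQ1 replicate 3 (0.11) or the block (0.14), with 0.0050 to 0.14 over its alternatives. Without the block those of ALPP (0.16, from 4.7e-05 at the lowest) and SLC7A7 (0.066, from 8.4e-06) ended. That of AXL ended without JQ1 replicate 2 (0.14), JQ1 replicate 3 (0.19), combination replicate 3 (0.18) or the block (0.81) and under quantile (0.13) or median ratio scaling (0.053) or plain empirical Bayes (0.075), with 0.021 to 0.81. MYC passed without either DMSO library (0.035 for both, with 0.035 to 0.69).

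The interaction of both drugs asks whether their joint change differed from the sum of the single ones. Of 32 E2F and DNA replication genes 9 lay above that sum (adjusted p of the list 0.14 with an estimated correlation), and DDR1 and PDGFRB lay below it. All these calls of genes ended in 5 of the alternative fits given below. The 8 largest positive values were in the checkpoint gene CLSPN (2.85, SE 0.37), CCNE2 (2.57), LYAR (1.97), the licensing factor CDC6 (1.88), the chromatin assembly factor CHAF1B (1.76), PHLDA1 (1.72), the mitotic inhibitor FBXO5 (1.51) and the spindle gene NUSAP1 (1.49). The 8 largest negative values were in ANGPTL7 (-8.94), DPEP1 (-5.95), CLIC3 (-3.81), MXRA8 (-3.70), FOLR1 (-3.64), TMEM156 (-3.26), TP53INP1 (-3.06) and MYLK, myosin light chain kinase (-3.02). ANGPTL7, DPEP1 and FOLR1 had almost no signal with DMSO, so JQ1 alone could hardly lower them on this scale. Their negative values may come from that floor, which was not tested. DDR1 (-1.54, SE 0.22), PDGFRB (-1.55, SE 0.27) and DUSP6 (-2.09) also passed. DUSP6 rested on 2.41 to 5.38 units with trametinib or both drugs, became -1.02 under quantile scaling (adjusted p = 0.37), and lost its call in 11 of 14 alternatives. SPRY4 (-2.61, adjusted p = 0.12), CCND1 (-0.96, adjusted p = 0.054), FOSL1 (-0.83), ETV4 (0.55), MYC (0.52), EGFR (-0.34), HEXIM1 (-0.29) and AXL (-0.23) did not in limma. SPRY4 passed without combination replicate 2 (-3.94, adjusted p = 0.035, with 0.035 to 0.69 over its alternatives). E2F genes were higher for 9 of 32 members (13 and 1 lower adjusted over the list alone; median 0.76, camera p = 4.3e-15, adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis genes were higher for 3 of 31 (12 adjusted over the list alone; median 0.51, p = 1.7e-11, adjusted p = 0.34 with an estimated correlation). Lysosome genes were lower for 3 of 28 (9 adjusted over the list alone; median -0.46, p = 0.0012, adjusted p = 0.53 with an estimated correlation).

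Limma called 111 genes positive and 428 negative for the interaction, 20.6% positive. The share was 52.2% under median ratio scaling (349 and 319 genes) and 41.8% under quantile scaling (168 and 234 genes), and the median gene stood at -0.16. The count of 539 became 1102 without DMSO replicate 2, 20 without trametinib replicate 2, 162 without combination replicate 2, 111 without DMSO replicate 3 and 96 without trametinib replicate 3. It was 0 in limma without JQ1 replicate 2, JQ1 replicate 3, combination replicate 3 or the replicate block and with plain empirical Bayes, where 2567, 1788, 2741, 923 and 3023 genes had an unadjusted p under 0.05. In these 5 fits all 19 named genes called for the interaction lost their calls, with adjusted p of 0.054 to 0.13 without JQ1 replicate 2, 0.12 to 0.28 without JQ1 replicate 3, and 0.066 to 0.12 without combination replicate 3. It was 0.58 to 0.73 without the block and 0.055 to 0.13 with plain empirical Bayes. Of these 19, 15 lost their calls without trametinib replicate 2 (up to 0.11), 10 without combination replicate 2 (up to 0.12), 9 each without DMSO replicate 3 (up to 0.093) and trametinib replicate 3 (up to 0.12). The number was 4 under quantile scaling (up to 0.37), 2 without DMSO replicate 2 (up to 0.074), 2 without the filter (up to 0.056), 1 with a pseudocount of 5 (up to 0.060) and 0 under median ratio scaling (0.012 to 0.049).

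How much of the trametinib response remained with JQ1 was measured in the replicate that did not choose the genes. Genes raised at least 2-fold in replicate 2 (2938 genes) were lower with both drugs than with trametinib in replicate 3 by a median of -0.47 on the log2 scale, against -0.18 for all genes. Of them 70.6% were lower, against 62.5%. For the 3074 genes raised in replicate 3 and measured in replicate 2, the median was -0.33 against -0.09, and 67.4% were lower against 57.0%. Their medians over DMSO were 1.59 and 1.54 with trametinib, 1.13 and 1.23 with both drugs, and 0.41 and 0.36 with JQ1 alone. Genes lowered at least 2-fold (1305 and 1239) had medians of -0.28 and -0.10 with both drugs against trametinib, which became -0.02 and 0.02 under median ratio scaling. The raised genes then had -0.34 and -0.30. In the fit of both replicates, from which they were chosen as well as measured, the 8 raised genes with the lowest values were ANGPTL7 (-8.57), FAM180A (-6.87), the matrix metalloproteinase MMP7 (-6.76), and WISP1 (-6.58), followed by the sulfotransferase SULT1B1 (-6.58), the monooxygenase FMO2 (-6.16), the decoy interleukin receptor IL1R2 (-5.89) and DPEP1 (-5.78). SULT1B1 stood at 172 and 81.4 units with trametinib and was listed at 0 in both JQ1 libraries, as was FMO2. Without the replicate block the calls of the 7 other than ANGPTL7 ended, with adjusted p of 0.068 for FAM180A, 0.056 for MMP7, 0.26 for WISP1, 0.052 for SULT1B1, 0.10 for FMO2, 0.11 for IL1R2 and 0.13 for DPEP1. The lowest over their alternatives were 0.00051, 0.00047, 0.00060, 0.00030, 0.00069, 0.0025 and 0.0017.

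Responses to the single drugs in SUM159 were related across genes, which are not independent replicates. JQ1 in replicate 2 and trametinib in replicate 3, which share no library, had a covariance of 0.33 (Pearson r = 0.32) over 12839 genes. JQ1 in replicate 3 and trametinib in replicate 2 had 0.37 (r = 0.30). Within replicates 2 and 3, where both share the DMSO library, the covariance was 0.37 (r = 0.35) and 0.53 (r = 0.45). Simulated unchanged groups gave a covariance of 0.089 from the shared library alone. Their r of 0.50 follows from sharing a control among groups of equal spread, so only the covariances can be compared. E2F genes fell with either drug (medians -3.11 with trametinib and -1.39 with JQ1), whereas HIST2H2BE rose with either (3.65 and 5.04) and DCN went opposite ways (4.01 and -1.97).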

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

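The tests of scaling and low values (raised genes against all genes, in refits that were planned), shrinkage and SUM159 alone in this part were chosen only after the result was seen.

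Differences between the responses of basal-like and claudin-low lines stand out because a test of the difference itself passed. Each subtype was represented by 3 lines with 2 libraries per treatment, and the p-values of that test may not measure the spread between lines. A called gene may therefore differ between these lines and not between the subtypes. The Wald test on the authors' deposited tables called 3492 genes, and the authors' deposited table for the subtypes called 3829. By the Wald test (basal-like minus claudin-low, from the authors' deposited tables) these included IL8 (4.02), MYEOV (3.50), E2F2 (2.84), CXCL1 (2.82), PTX3 (2.77), E2F8 (2.66), CCNE2 (2.63), CLDN1 (2.53), DUSP6 (2.36) and CCND1 (1.28). On the negative side of the authors' deposited tables were LAMA3 (-2.52), C1orf198 (-2.48), DEPDC6 (-2.41), CLIC3 (-2.35), C10orf10 (-2.24), RCAN2 (-2.22), KIF26B (-2.20), EFHD1 (-2.09), DDR1 (-1.39), PDGFRB (-1.34), AXL (-0.64) and HEXIM1 (-0.54). Of these, DUSP6 (-0.52, adjusted p = 0.61), CCND1 (-0.87, adjusted p = 0.26) and PDGFRB (1.05, adjusted p = 0.13) were not called in the authors' deposited table for the subtypes, which is claudin-low minus basal-like. PDGFRB had a base mean of only 7.02 in basal-like lines.

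For claudin-low minus basal-like, the authors' deposited table gave positive values for CALB1 (4.78), DUSP2 (4.26), MLXIPL (4.15), ESPN (4.13), PDGFB (4.09), NTSR1 (3.85), SPRY4 (1.85), DDR1 (1.55), AXL (0.69) and HEXIM1 (0.56). Negative values in the authors' deposited table were those of IL8 (-4.06), FAM111B (-3.79), SERPINB4 (-3.55), RNF17 (-3.53), MYB (-3.47), E2F2 (-3.21), E2F8 (-3.18) and CXCL1 (-3.12). By the Wald test on the authors' deposited tables ESPN (adjusted p = 0.17), SPRY4 (0.10) and SERPINB4 (0.0504) were not called. As lists in the authors' deposited table, E2F and DNA replication (median -2.01), mitosis (-2.09), polyadenylated histones (-0.65), sterol synthesis (0.34) and ribosome biogenesis (-0.21) passed camera. The last 2 did not pass at a preset correlation of 0.05 (adjusted p = 0.11 and 0.12) on the authors' deposited table.

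The interaction in SUM159 stands out because the effect of trametinib differed with and without JQ1 by a test, for 539 genes. The count was 0 without JQ1 replicate 2, JQ1 replicate 3, combination replicate 3 or the replicate block and with plain empirical Bayes, and the 19 genes named here lost their calls in those 5 fits. DUSP6 lost its call in 11 of 14 alternatives and fell to -1.02 under quantile scaling. Positive values were those of CLSPN (2.85), CCNE2 (2.57), LYAR (1.97), CDC6 (1.88), CHAF1B (1.76), PHLDA1 (1.72), FBXO5 (1.51) and NUSAP1 (1.49). Negative ones were those of ANGPTL7 (-8.94), DPEP1 (-5.95), CLIC3 (-3.81), MXRA8 (-3.70), FOLR1 (-3.64), TMEM156 (-3.26), TP53INP1 (-3.06), MYLK (-3.02), DUSP6 (-2.09), PDGFRB (-1.55) and DDR1 (-1.54). ANGPTL7, DPEP1 and FOLR1 had almost no signal with DMSO, so JQ1 alone could hardly lower them, and their values may come from that floor. Among the lists, camera passed E2F and DNA replication (median 0.76, adjusted p = 0.14 with an estimated correlation) and mitosis (0.12, adjusted p = 0.78 with an estimated correlation). It also passed interferon response (-0.84, adjusted p = 0.45 with an estimated correlation), antigen presentation (-0.52, adjusted p = 0.42 with an estimated correlation) and extracellular matrix (-0.62, adjusted p = 0.30 with an estimated correlation). At a preset correlation of 0.05 the adjusted p was 0.15 for mitosis, 0.12 for interferon response, 0.063 for antigen presentation and 0.082 for extracellular matrix. Ribosome biogenesis (0.51, adjusted p = 0.34 with an estimated correlation) and lysosome genes (-0.46, adjusted p = 0.53 with an estimated correlation) passed as well. Camera compares a list with other genes, and the median gene stood at -0.16 for the interaction. A list that passed is therefore not shown to differ from the sum of the single drugs.

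A first pattern is the larger fall of E2F and mitosis genes in claudin-low lines, with medians over 62 genes of -0.15 in basal-like and -1.88 in claudin-low lines in the authors' deposited tables. Unequal shrinkage of their fold changes is argued against by the subtype table, a separate fit of the same libraries whose standard errors show no such limit. In the authors' deposited table for the subtypes all 62 genes were lower in claudin-low lines, with a median of -2.08, quartiles of -2.32 and -1.82, and a smallest difference of -0.87. A response of SUM159 alone cannot be told apart from one of all 3 claudin-low lines, because the tables hold no values per line, and the same genes had a median of -2.98 in SUM159 at 100 nM in the authors' deposited table. A difference between the lines' subtypes is the biological explanation that the design names, and it stays open, as untested against differences between single lines.

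A second pattern is the fall back of trametinib-raised genes when JQ1 was added, by a median of -0.47 in replicate 3 and -0.33 in replicate 2. Under median ratio scaling the raised genes lay below all genes by -0.37 in replicate 3 and -0.30 in replicate 2. This test cannot decide on scaling as a cause, because a single factor per library shifts raised genes and all genes alike. Their difference could change only through the choice of genes. Among genes with a mean of at least 100 over the 8 libraries, the raised genes lay below all genes by -0.17 in replicate 2 and -0.12 in replicate 3. This does not decide on low values as a cause, because a gene can pass that mean through its trametinib libraries alone. The size depended on the filter, because with all genes above a mean of 10 these differences were -0.25 and -0.29. An effect of JQ1 on genes raised by MEK inhibition remains a hypothesis, found and tested on the same 8 libraries.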

How the results depend on the processing

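No test in this part was chosen only after the result was seen. Named genes kept their side of the threshold in 2443 pairs of gene and alternative, 232 fell short of the threshold and 18 newly passed. Direction was compared only for genes called in the main setting, and 0 of these reversed. Stricter limits and base mean minima leave the deposited fold changes and their differences as they are, so no reversal was possible there. The cause was not tested where a result changed, except that leaving out a library leaves fewer samples, and a lone library is then assumed to vary like the other groups. Depth of 12.5 megareads in the shallowest library limits low genes, since 1 read was worth 1.19 units there.

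Without the replicate block, calls became 2860 for trametinib against DMSO, 118 for JQ1 against DMSO, 3167 for both drugs against DMSO, 12 against trametinib, 509 against JQ1 and 0 for the interaction. Plain empirical Bayes gave 0 for the interaction. With each library left out in turn, the ranges were 5447 to 7248, 1010 to 3956, 5852 to 7039, 1033 to 3717, 1419 to 4365 and 0 to 1102 in the same order. A log2 minimum of 1 left 539 genes in basal-like lines, 2408 in claudin-low lines, 1112 in the subtype table and 2876 for 100 nM in the authors' deposited tables. An adjusted p under 0.01 left 2424 in the authors' deposited table for the subtypes. Pseudocount, filter, quantile and median ratio scaling kept each SUM159 count, summed over both directions, within 1.5 times. So did an adjusted p under 0.01 and a base mean minimum of 100 for the other counts from the authors' deposited tables. Some counts by direction moved further under median ratio scaling. Positive interaction calls went from 111 to 349 and negative ones from 428 to 319. With both drugs against trametinib, higher genes went from 917 to 1623 and lower ones from 2231 to 1693.

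The fall back of raised genes chosen in replicate 2 became -0.33 with a 1.5-fold choice, -0.24 with a mean of at least 100 and -0.34 under median ratio scaling, and that of genes chosen in replicate 3 became -0.23 with a mean of at least 100. For lowered genes under median ratio scaling it became -0.025 (chosen in replicate 2) and 0.022 (chosen in replicate 3, the 1 reversed sign). Of 50 list calls in SUM159, 0 held with an estimated correlation, 38 with a preset correlation of 0.05, and fry gave 69, while 30 of 41 calls on the authors' deposited tables held at 0.05. The overlap between subtypes and the relation of JQ1 to trametinib kept their direction under every alternative.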

Other observations

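The test of depth in this part was chosen before the result was seen.

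Part of the histone, sterol, lysosome and antigen presentation genes rose with trametinib in SUM159. The authors' deposited table for 100 nM trametinib had 7 of 14 polyadenylated histone genes higher and none lower (7 adjusted over the list alone; camera p = 0.0020). In the fit of replicates 2 and 3, 12 of 21 rose and 3 fell (12 and 3 adjusted over the list alone; median 1.13, camera p = 0.040, 0.15 at a preset correlation of 0.05, adjusted p = 0.34 with an estimated correlation). The list did not pass in the authors' deposited table for claudin-low lines (10 lower and 6 higher of 24, or 11 and 6 adjusted over the list alone; p = 0.090). Sterol synthesis genes rose for 8 of 25 (8 adjusted over the list alone; p = 0.0050, and 0.053 at a preset correlation of 0.05) in the authors' deposited table. In replicates 2 and 3, trametinib alone raised 23 of 28 lysosome and autophagy genes with 1 lower (23 and 1 adjusted over the list alone; median 1.14, camera p = 1.2e-05, adjusted p = 0.45 with an estimated correlation). Antigen presentation genes rose for 14 of 16 with 1 lower (14 and 1 adjusted over the list alone; median 1.16, p = 0.0046, adjusted p = 0.36 with an estimated correlation). In the authors' deposited table for 100 nM 8 of 16 rose and 1 fell (8 and 1 adjusted over the list alone; p = 0.040, and 0.12 at a preset correlation of 0.05). With both drugs against JQ1, sterol synthesis genes rose for 16 of 25 with 1 lower (17 and 1 adjusted over the list alone; median 0.77, p = 2.8e-05, adjusted p = 0.52 with an estimated correlation).

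More genes lay above 0 with trametinib alone than in any other library of the same replicate. In replicate 2 there were 16154, against 15614 in the highest other library, and in replicate 3 there were 16169 against 15333. Depth is argued against as the cause, since after thinning to 29.4 and 12.5 megareads 16020 genes remained against 15534, and 15727 against 14879. The smaller of these differences was 486. No biological explanation was tested.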
